A study of Homo sapiens with 4 samples.

How the data were processed

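Poly(A)-selected RNA of 4 samples of the human neuroblastoma line SH-SY5Y was sequenced, 2 untreated controls and 2 samples given shock wave treatment (SWT), and RNA was isolated 6 h after treatment, per the labels' protocols. Groups and replicate numbers were taken from the sample labels. The sample protocols describe cells treated directly, in flasks held in a water bath at 37 °C, at 7 cm from the applicator, with 300 impulses of 0.08 mJ/mm2 at 3 Hz. The design text of the series speaks instead of exosomes from shock wave treatment, and the sources used here do not settle which was done. Nothing in the labels says that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

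The authors deposited a table of raw counts per gene symbol for 28058 genes. Trimmomatic 0.36, FastQC 0.11.5, STAR 2.5.3a, HTSeq and DESeq2 are named in the submitters' processing notes without a role, together with the build hg38. The gene annotation and the strand setting of the counting were not given in the sources used here. The library kit was a stranded mRNA kit, per the labels' protocols. The authors also deposited a table of log2 values for 17151 genes, whose differences between libraries were 0.429 times those of the log2 counts, as in a shrunken log transform. That table leaves out 585 counted genes named as antisense. A log2(value + 1) transform had been planned for it, and because its values are already logarithms they were tested as they stand.

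Counts were tested with edgeR 4.0.16 in R 4.3.3, using TMM factors (0.997 to 1.004), filterByExpr with the group, and the quasi-likelihood F-test with Benjamini-Hochberg adjustment over the 12399 genes kept, at a threshold of 0.05. The biological coefficient of variation was 4.32%. CPM values use the TMM-scaled library sizes. Standard errors were calculated from the same fit, as the absolute log2 fold change over the square root of the F statistic. The 95% intervals multiply them by a t quantile, so both are approximate. For 31 gene lists fixed before the data were examined, camera in limma 3.58.1 was run on log2 CPM (prior count 2) with a preset correlation of 0.01, over the 28 lists with at least 5 tested members. Camera with an estimated correlation and fry were run beside it. Exact Clopper-Pearson and exact Poisson intervals and the limit that a count of 0 allows (3 counts) cover counting error only, and so do Fisher exact tests on counts of 2 libraries. Coordinates are those of GENCODE release 29 on GRCh38, the same assembly as hg38, matched by symbol for 40 of 41 named genes. Python 3.11.15 and matplotlib 3.10.9 drew the plots.

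The named genes follow a rule fixed before the data were examined. Where fewer than 5 genes passed in a direction, the 8 with the smallest p-values were taken and given as values that did not pass. TLR3 was named whatever its result. For each list passing camera the 4 members with the smallest p-values were added, and for other lists up to 3 where a member passed over the list alone. Genes named outside this rule were chosen after their values were seen, as were the list of 26 heart muscle genes and the identity genes shown one by one.

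Alternatives fixed before the data were examined were DESeq2 size factors and upper-quartile scaling, no filter, a mean count of at least 50, the replicate number as a block, leaving out each library, DESeq2 1.42.0, limma-voom, limma on the deposited log2 values, robust empirical Bayes, a threshold of 0.1 and a log2 fold change of at least 1. Added after the data were seen were a crossed pairing, removal of each library's trend with transcript length and GC content (known for 98.1% of tested genes), leaving out the heart muscle genes, and list medians between control replicate 1 and SWT replicate 2. Length and GC content were taken from the longest GENCODE transcript of each gene name.

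The fits were tested on simulated counts for the SWT and control comparison over 12399 genes, drawn from the real means, library sizes and dispersion trend with 200 genes changed. In 10 simulations edgeR recovered 45% of genes changed 1.25-fold, 71.8% at 1.5-fold, 89.8% at 2-fold and 97% at 3-fold, and 3.80% of its calls were false. The simulated genes had no spread around the dispersion trend, and the simulated libraries had no GC trends and no heart muscle transcripts of their own. These shares therefore need not hold for the real libraries. In 10 further simulations the 76 ribosomal protein genes were shifted by -0.1 on the log2 scale. Camera with the preset correlation called that list in 10, camera with an estimated correlation in 0 and fry in 2, and 0 of 270 unshifted lists were called. Simulated genes were drawn independently, so false calls from correlated list members could not arise. In the real data the estimated correlation was 0.092 for immediate early genes and 0.188 for NF-kB targets, above the preset 0.01. It was -0.011 for ribosomal protein genes and -0.0087 for respiratory chain genes, below the preset.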

Results

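Gene expression was measured by poly(A) RNA sequencing in cells labelled as SH-SY5Y, a human neuroblastoma line, 6 h after shock wave treatment (SWT). The sample protocols describe SWT as a train of pressure pulses applied to flasks in a water bath, while the series design text speaks of exosomes. There were 2 untreated control samples and 2 SWT samples. Total counts were 11647603 in control replicate 1, 9888263 in control replicate 2, 10043697 in SWT replicate 1 and 11686808 in SWT replicate 2. Between 15715 and 15988 genes had at least 1 count in a library. A count of 0 allows up to 0.258 to 0.303 CPM, depending on the library.

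All 4 libraries carried most of the mesenchymal genes at 10 CPM or more and a minority of the noradrenergic genes. Of the 30 mesenchymal neuroblastoma markers fixed in advance, 25 reached 10 CPM in every library. The intermediate filament gene VIM stood at 3254 ± 92.9 CPM, the collagen genes COL1A1 and COL3A1 at 3026 ± 272 and 2917 ± 315 CPM, and the transcription factor gene PRRX1 at 466 ± 17.2 CPM (SD, n = 4). Of the 29 noradrenergic identity genes, 5 reached 10 CPM in every library, HAND2, KLF7, TBX2, GATA2 and SATB1, while 20 stayed under 1 CPM in every library and 15 had 0 counts in all 4. Together the 29 genes summed to 170 to 177 CPM per library. The genes without a count included PHOX2A, encoding a transcription factor of noradrenergic neurons, TH and DBH, enzymes of catecholamine synthesis, the chromogranin gene CHGA and MYCN. HAND2 was present at 52.1 ± 2.24 CPM and ISL1 at 5.76 ± 0.773 CPM (SD, n = 4). Members under 1 CPM in every library numbered 12 of 20 endothelial, 10 of 15 glial and Schwann cell and 12 of 16 leukocyte markers.

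**Figure D1:**
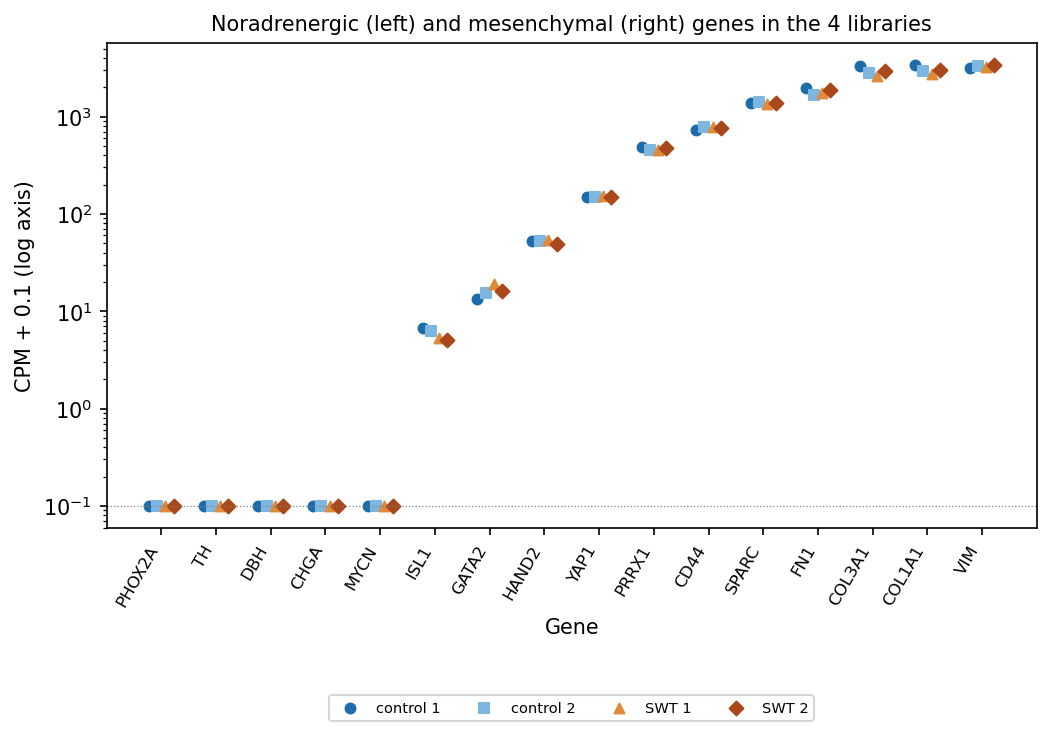
CPM plus 0.1 on a log axis for 8 noradrenergic genes (left) and 8 mesenchymal genes (right), with 1 point per library and the dotted line at 0 CPM. PHOX2A, TH, DBH, CHGA and MYCN lie at 0 counts in all 4 libraries, while VIM averages 3254 CPM.

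Heart muscle transcripts were present in 1 library of each group. Over 26 heart muscle genes, control replicate 2 held 4230 counts (428 CPM) and SWT replicate 1 held 482 counts (47.9 CPM), against 87 in control replicate 1 and 92 in SWT replicate 2. The atrial myosin gene MYH6 had 952 counts in control replicate 2 and 27 in SWT replicate 1, and NPPA, encoding atrial natriuretic peptide, had 626 and 7. The ventricular myosin gene MYH7 made up 3.55% of MYH6 and MYH7 counts in control replicate 2 (95% exact Clopper-Pearson interval 2.48% to 4.90%) and 67.1% in SWT replicate 1 (55.8% to 77.1%). In control replicate 2, 31 genes with at least 20 counts stood at least 5-fold above every other library, 18 of them on the heart list, and 0 genes did so in any of the other libraries.

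**Figure D2:**
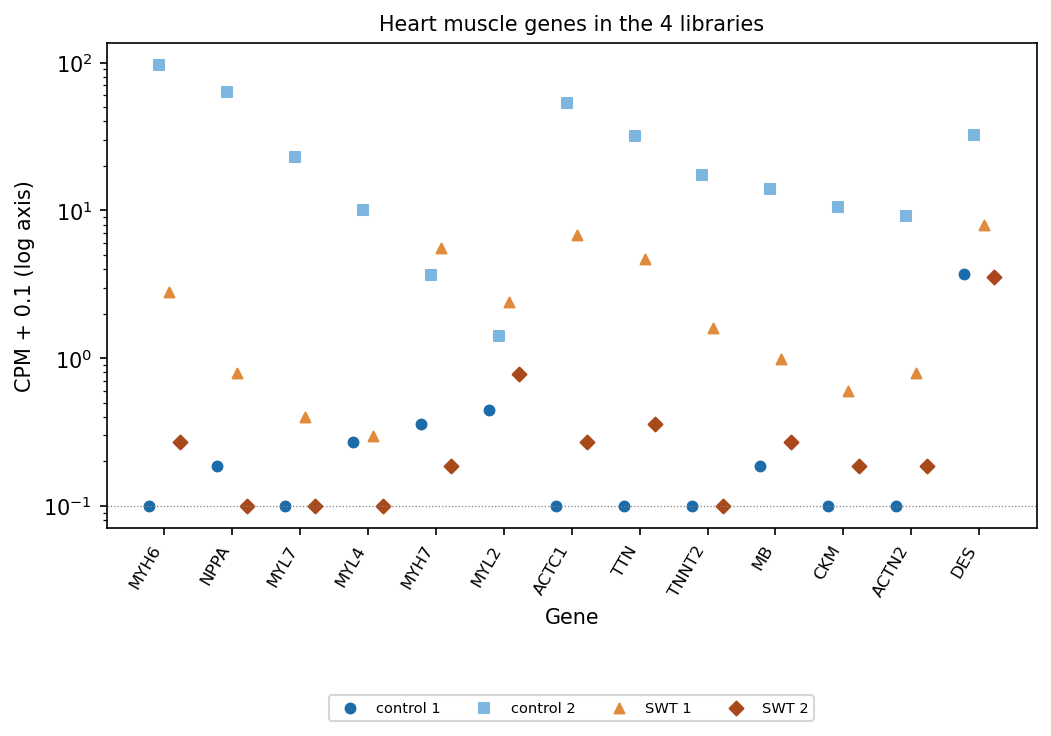
CPM plus 0.1 on a log axis for 13 heart muscle genes, with 1 point per library and the dotted line at 0 CPM. Control replicate 2 has the highest level for most genes, with MYH6 at 96.3 CPM, and SWT replicate 1 the highest for MYH7 and MYL2.

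Libraries differed along GC content both within and between the groups. Over 6320 genes with a mean log2 CPM above 5, the difference between the control libraries (replicate 2 minus 1) correlated with GC content across genes at a Spearman rho of -0.482, and that between the SWT libraries (replicate 2 minus 1) at 0.379. SWT minus control gave -0.401, and the difference between control replicate 1 with SWT replicate 2 and the other two libraries gave 0.541. Across the groups, SWT replicate 2 minus control replicate 1 gave -0.422 and SWT replicate 1 minus control replicate 2 gave -0.194, so neither pair was matched on GC content. With transcript length, SWT minus control gave 0.287. Genes are not independent replicates, and no p-value was attached. The 2 control libraries differed by a chi-square of 3.80 per degree of freedom and the 2 SWT libraries by 1.72, against 2.30 to 3.83 for pairs across the groups, so no pair agreed within sampling noise.

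The comparison of SWT with control asks what differs between treated and untreated samples, and the series title names Toll-like receptor 3. No gene passed the test. The receptor gene TLR3 (chromosome 4, 186069152 to 186088069) stood at 19.2 ± 0.792 CPM in control and 20.4 ± 1.58 CPM in SWT (SD, n = 2 each), a log2 fold change of 0.09 (SE 0.11, edgeR adjusted p = 0.941). With each library left out in turn it ranged from 0.0092 without SWT replicate 1 to 0.17 without SWT replicate 2, and was 0.13 without control replicate 1 and 0.047 without control replicate 2. Among genes higher in SWT by value, ID1, an inhibitor of basic helix-loop-helix factors (chromosome 20, 31605283 to 31606515), had 50.8 ± 1.80 CPM in control and 66.3 ± 3.55 CPM in SWT (SD, n = 2 each), a log2 fold change of 0.39 (SE 0.07, edgeR adjusted p = 0.759). SLC7A11, the cystine transporter gene (chromosome 4, 138164097 to 138242349), had a log2 fold change of 0.34 (SE 0.07), with 182 ± 23.8 CPM in control and 229 ± 0.740 CPM in SWT (SD, n = 2 each), and 0.21 without control replicate 1. Values for the other genes of this direction were 0.91 for ESM1, 0.54 for AOX1, 0.45 for LETM2, 0.35 for IGFBP3, 0.28 for PODXL (0.17 without control replicate 1) and 0.23 for THBS1, the thrombospondin gene.

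Among genes lower in SWT by value were the mitochondrial ribosomal RNA genes RNR2 and RNR1, with log2 fold changes of -0.20 (SE 0.04) and -0.24 (SE 0.06), whose reads can be shared with nuclear copies. FTL, the ferritin light chain gene with processed pseudogenes, stood at -0.15 (SE 0.04), the transporter gene ABCC3 at -0.24, ACP6 at -0.44, PRR19 at -1.05 and LINC01410 at -2.29. MYH6 (chromosome 14, 23381990 to 23408277) stood at -5.11 (SE 1.30), from counts of 0 and 952 in control and 27 and 2 in SWT, at 6.92 without control replicate 2 and at -8.01 without SWT replicate 1. These genes had edgeR adjusted p-values from 0.759 to 0.769.

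**Figure D3:**
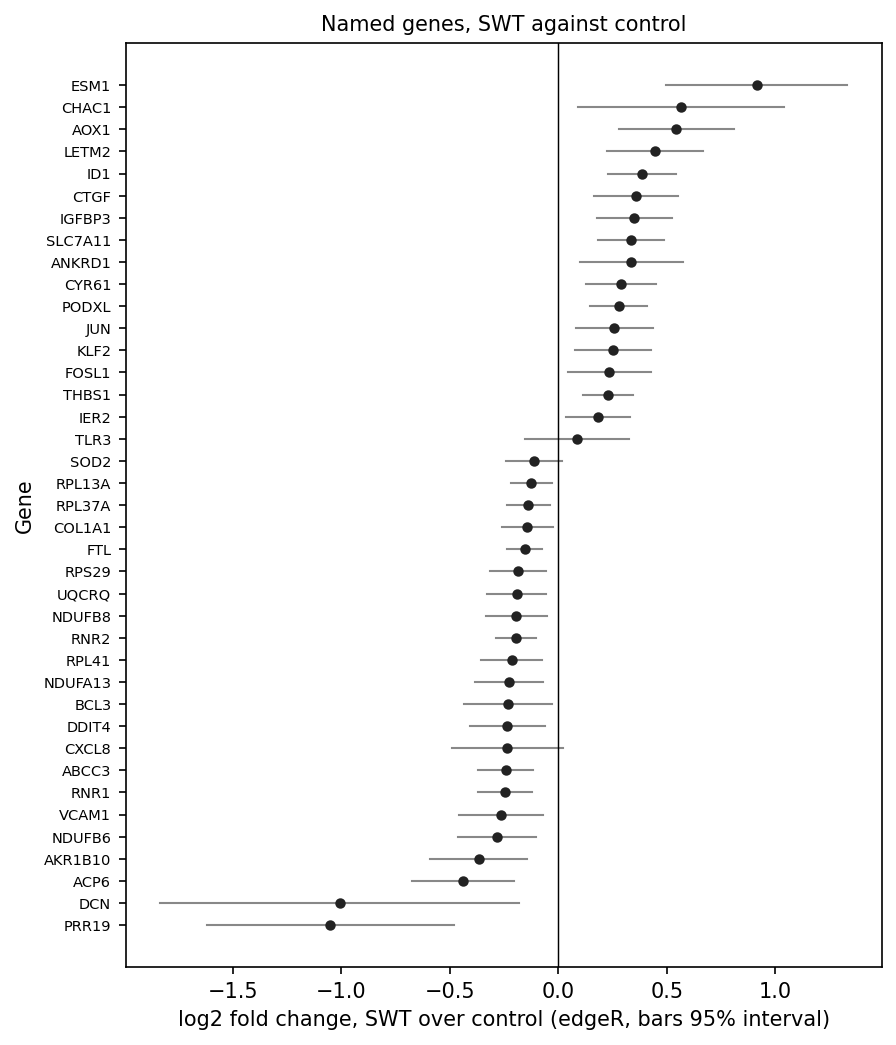
Log2 fold change of SWT over control with its 95% interval (edgeR) for the named genes except MYH6 and LINC01410, whose intervals are much wider. No gene passed the test over all genes; ESM1 has the highest value, 0.91, and PRR19 the lowest, -1.05.

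With edgeR's quasi-likelihood test, 0 of 12399 genes were higher and 0 lower, with 715 genes at an unadjusted p under 0.05 (348 higher, 367 lower) where 620 are expected by chance. DESeq2 gave 0 genes (116 of 17737 unadjusted), limma-voom 0 (721 of 12399) and limma on the deposited log2 values 0 (847 of 17151). The 620 expected by chance holds for 12399 genes, and chance gives more for the larger sets, so 847 cannot be set against it. DESeq2's 116 lies far below chance, so its p-values ran high and its 0 genes add little. The 95% interval lay within 1 log2 unit of 0 for 11570 genes (93.3%) and within 0.5 for 9616 (77.6%). Both SWT libraries lay on the same side of both controls for 35.3% of genes, where chance gives 33.3%. The count of 0 rested on having all libraries: without control replicate 1 edgeR called 123 genes, 23 on the heart list, without control replicate 2 it called 203, 4 on that list, without SWT replicate 1 it called 44, 22 on that list, and without SWT replicate 2 it called 17, 13 on that list. In those fits the lone library of a group was assumed to vary like the other group. The count of 0 also rested on the filter: with all 4 libraries and no filter, edgeR called 63 genes, 21 on the heart list. Genes that the filter had kept were among them, with nearly unchanged log2 fold changes. Examples were CTGF at 0.36 (edgeR adjusted p = 2.73e-06), SLC7A11 at 0.34 (2.25e-05) and RNR2 at -0.19 (0.00169). The added calls were therefore not only of genes that the filter removes.

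Cytosolic ribosomal protein genes fell as a list after SWT (camera adjusted p = 3.83e-06). The call was lost with an estimated correlation (adjusted p = 0.560) and with fry (adjusted p = 0.126). Those tests called 0 and 2 of 10 simulations with a true shift of this list by -0.1, so the loss decides little. Of 76 tested members, 68 lay below 0, with a median log2 fold change of -0.073, and none passed the test alone. RPL41 stood at -0.21, RPS29 at -0.19, RPL37A at -0.14 and RPL13A at -0.12; ribosomal protein genes have many pseudogenes, so single values are uncertain. The median was -0.080 between control replicate 1 and SWT replicate 2 and -0.062 between control replicate 2 and SWT replicate 1. It was -0.013 between the controls and 0.0015 between the SWT libraries. With the length and GC trend of each library removed it was -0.044 (camera adjusted p = 1.57e-04).

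Nuclear-encoded respiratory chain genes also fell as a list (camera adjusted p = 0.00951), with 56 of 70 members below 0 and a median of -0.048. The call was lost with an estimated correlation (adjusted p = 0.668) and with fry (adjusted p = 0.128). Those tests seldom found a simulated shift of the ribosomal list, and their power for the respiratory chain list was not simulated. NDUFB6, NDUFA13 and NDUFB8, of complex I, stood at -0.28, -0.23 and -0.19, and UQCRQ, of complex III, at -0.19. Without control replicate 1, NDUFA13 stood at -0.14 and UQCRQ at -0.12, and without SWT replicate 1 NDUFA13 stood at -0.14. The median was -0.048 between control replicate 1 and SWT replicate 2 and -0.045 between control replicate 2 and SWT replicate 1. It was -0.016 between the controls and 0.0041 between the SWT libraries. The call was also lost without a filter (adjusted p = 0.0519), after removal of the length and GC trend (0.0679), and without control replicate 1 (0.103), SWT replicate 1 (0.115) or SWT replicate 2 (0.163).

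Immediate early genes rose as a list (camera adjusted p = 0.0239), with 15 of 19 members above 0 and a median of 0.066. The call was lost with an estimated correlation (adjusted p = 0.833) and with fry (adjusted p = 0.722). JUN and FOSL1, subunits of the AP-1 factor, stood at 0.26 and 0.24, KLF2 at 0.25 and IER2 at 0.18. FOSL1 stood at 0.042 without control replicate 1 and 0.45 without control replicate 2, and JUN at 0.14 without SWT replicate 2. The median was 0.173 between control replicate 1 and SWT replicate 2 and 0.037 between control replicate 2 and SWT replicate 1. The controls differed by a median of 0.084, more than the groups did, and the SWT libraries by 0.020. The call was also lost without a filter (adjusted p = 0.160) and without control replicate 1 (0.638), SWT replicate 1 (0.113) or SWT replicate 2 (0.122).

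NF-kB targets and cytokines fell as a list (camera adjusted p = 0.0257), with 17 of 23 members below 0 and a median of -0.083. The call was lost with an estimated correlation (adjusted p = 0.833) and with fry (adjusted p = 0.722). The adhesion molecule gene VCAM1 stood at -0.27, the chemokine gene CXCL8 at -0.23, BCL3 at -0.23 and SOD2 at -0.11. CXCL8 stood at -0.41 without control replicate 1 and -0.044 without control replicate 2, BCL3 at -0.15 without control replicate 1, and VCAM1 at -0.15 without SWT replicate 1 and -0.40 without SWT replicate 2. The median was -0.011 between control replicate 1 and SWT replicate 2 and -0.115 between control replicate 2 and SWT replicate 1. It was 0.048 between the controls and 0.071 between the SWT libraries (replicate 2 minus 1). The call was also lost after removal of the length and GC trend (median -0.042, adjusted p = 0.0679) and without control replicate 2 (0.438) or SWT replicate 1 (0.562).

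**Figure D4:**
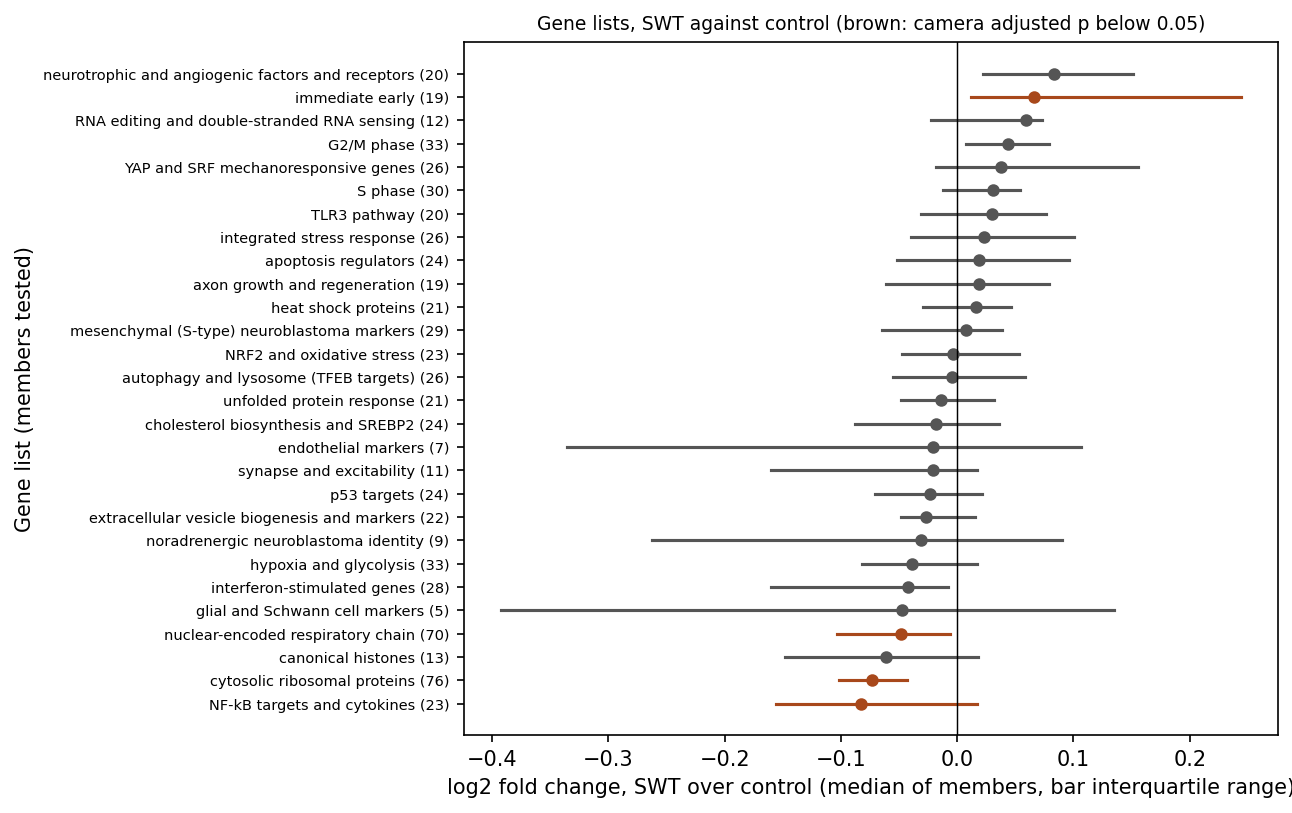
Median log2 fold change of SWT over control (points) and interquartile range (bars) for the 28 lists tested, with the number of members in brackets and lists with a camera adjusted p below 0.05 in brown. Medians lie close to 0: ribosomal proteins at -0.073, respiratory chain at -0.048, NF-kB targets at -0.083 and immediate early genes at 0.066.

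Lists tied to the receptor and to interferon did not pass camera over all genes tested. The TLR3 pathway list had 13 of 20 members above 0 and a median of 0.030 (adjusted p = 0.716), and interferon-stimulated genes had 21 of 28 below 0 and a median of -0.042 (adjusted p = 0.116), a list that passed as lower with a mean count of at least 50 (0.0438). RNA editing and double-stranded RNA sensing genes gave an adjusted p of 0.402. IFNB1, the interferon beta gene, had 0 counts in all 4 libraries.

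The mechanoresponsive list of YAP and SRF targets had 16 of 26 members above 0 (camera adjusted p = 0.114). Its adjusted p was 0.0181 without control replicate 2, 0.726 without control replicate 1, 0.128 without SWT replicate 1 and 0.535 without SWT replicate 2. Adjusted over the list alone, 2 members passed in edgeR, CTGF at 0.36 and CYR61 at 0.29 (adjusted p = 0.0201 for both), against 0 over all genes tested. CTGF was higher by 0.60 in SWT replicate 2 than in control replicate 1 and by 0.14 in SWT replicate 1 than in control replicate 2, and CYR61 by 0.47 and 0.12. Without control replicate 1, CTGF stood at 0.15 and CYR61 at 0.13, and without control replicate 2 at 0.59 and 0.47. ANKRD1 stood at 0.34, at 0.070 without control replicate 1 and at 0.65 without control replicate 2. Adjusted over the list alone, SLC7A11 passed in the integrated stress response list (0.00561) and THBS1 in the mesenchymal list (0.0180). SLC7A11 stood at 0.21 without control replicate 1. In the NRF2 list 1 member passed upwards over the list alone, the thioredoxin reductase gene TXNRD1, and 3 downwards, FTL, ABCC3 and the reductase gene AKR1B10 (-0.37).

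The remaining lists did not pass camera over all genes tested. Adjusted p-values were 0.0923 for both G2/M phase genes and neurotrophic and angiogenic factors, 0.402 for S phase, synapse and excitability, and cholesterol biosynthesis, and 0.432 for canonical histones and the integrated stress response. Without control replicate 2, G2/M phase genes (0.0181) and neurotrophic and angiogenic factors (0.0396) passed as higher. With a mean count of at least 50, neurotrophic and angiogenic factors passed as higher and canonical histones as lower (0.0438 for both). They were 0.564 for extracellular vesicle genes, 0.568 for hypoxia and glycolysis and for p53 targets, 0.676 for noradrenergic identity, and 0.707 for NRF2. They were 0.716 for heat shock proteins, the unfolded protein response, apoptosis regulators and glial markers, 0.870 for endothelial markers, 0.933 for mesenchymal markers, 0.938 for axon growth and 0.968 for autophagy and lysosome. Median, mean and test differed in sign for heat shock proteins, mesenchymal markers and autophagy genes. The heat shock list holds CRYAB, which stood at -1.58 with all libraries and at 6.81 without control replicate 2. Metallothioneins, mitochondrially encoded genes and leukocyte markers had fewer than 5 tested members. No list passed with an estimated correlation or with fry's directional test, and fry's test for change in either direction gave synapse and excitability alone (adjusted p = 0.0457).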

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

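Alternatives added after the data were seen were the crossed pairing, the removal of the length and GC trend, the fit without heart muscle genes and the pair of control replicate 1 with SWT replicate 2. Counts of 0 genes higher and 0 lower held with DESeq2 size factors, upper-quartile scaling, a mean count of at least 50, DESeq2, limma-voom, the deposited log2 values, robust empirical Bayes, a threshold of 0.1, a log2 fold change of at least 1, no heart muscle genes and no length and GC trend. Without a filter edgeR called 20 genes higher and 43 lower, 21 of the latter on the heart list. Leaving out each library in turn gave 2 to 106 genes higher and 15 to 97 lower, from fits with 1 sample fewer. The correlation of same-numbered deviations was -0.264, which gave no sign that the replicate numbers pair the samples. It rests on 1 difference per group, and those differences followed opposite GC trends (Spearman rho -0.482 and 0.379), so a pairing is not excluded. With the replicate block 1 gene was lower, MYH6, and 3 of the 4 list calls were kept, that of NF-kB targets being lost (adjusted p = 0.0594). The crossed pairing, chosen because that correlation was negative, called 55 genes higher and 42 lower, and 2 lists higher and 3 lower. A block chosen in this way from the same data makes the remaining spread smaller, so these calls decide nothing about treatment.

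The main fit called 1 list higher and 3 lower. Lists higher numbered 0 without a filter, 2 at a mean count of at least 50, with neurotrophic factors gained, and 0 to 4 when each library was left out. Lists lower numbered 5 at a mean count of at least 50, with interferon-stimulated genes and histones gained, 1 with the length and GC trend removed and 1 to 2 when each library was left out. An estimated correlation and fry each gave 0 higher and 0 lower. Ribosomal protein genes were called lower in 12 of 12 alternatives that kept the preset correlation, with adjusted p from 5.42e-07 to 0.0108. Of 651 combinations of named gene and setting, 571 kept direction without passing, 79 passed in the same direction and 1 reversed, MYH6, which ranged from -8.01 without SWT replicate 1 to 6.92 without control replicate 2, the library that holds its counts. The cause of the other shifts was not tested. Splits of the 4 libraries into 2 and 2 number 3, and all 3 reach the real count of 0 genes by construction, so they decide nothing; the highest other called 14 genes, 9 of them on the heart list.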

Other observations

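The fit without control replicate 2 and camera, with the preset or an estimated correlation, were fixed before the data were examined. For a second list of heart muscle genes, the bound of the ratio was written before its counts were examined. The remaining tests on these data, among them the removal of the length and GC trend, were chosen after the results were seen.

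With control replicate 2 left out, edgeR called 203 genes, set against control replicate 1 alone, of which 7 higher genes were on the YAP and SRF list and 4 on the heart list. ANKRD1 stood at 0.65, F3, the tissue factor gene, at 1.08 and DKK1, a Wnt antagonist gene, at 1.25, while COL3A1 stood at -0.27 and DDIT4 at -0.37. With all libraries these genes stood at 0.34, 0.50, 0.75, -0.15 and -0.23, in the same order. CRYAB, not on the heart list, stood at 6.81 without control replicate 2 and at -1.58 with all libraries. ACTC1, on that list, changed sign likewise (8.19 and -2.97), so counts of genes on the heart list may be too low. ANKRD1 had 178 CPM in control replicate 1, 267 in control replicate 2, and 279.6 and 280.2 in the SWT libraries, so the log2 gap between the controls, 0.58, exceeded that between the groups, 0.34. COL1A2 averaged 2.99 CPM over the 4 libraries against 3026 for COL1A1, its partner chain in type I collagen.

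Heart muscle genes reached 428 CPM in control replicate 2 against 7.50 in control replicate 1, and 47.9 CPM in SWT replicate 1 against 7.90 in SWT replicate 2, which argues against the treatment as their cause. The MYH7 share of 67.1% in SWT replicate 1 against 3.55% in control replicate 2 argues against 1 heart source for both (two-sided Fisher exact p = 2.02e-47, which covers counting error only). The second list, of 24 heart muscle genes, missed the bound set for it: its 22 members under 10 CPM had a ratio of 1.69 (95% exact interval 1.45 to 1.98) in control replicate 2 over control replicate 1 and SWT replicate 2, below the 2 that RNA or reads from heart muscle were to give. That bound was ill-chosen, since 9 members expressed at baseline carried 391 of the 396 counts in those libraries, so heart muscle RNA may be a source but was not established. For muscle genes switched on in the cultured cells alone, 18 endothelial genes under 10 CPM gave a ratio of 1.29 (1.08 to 1.54). The lower bound below 1.5 is what that explanation predicted, but 7 of the genes carried 350 of the 358 base counts, so this test decides as little. The 11 endothelial genes with at most 1 count in control replicate 1 and in SWT replicate 2 had 4 counts in each. They had 32 in control replicate 2 and 6 in SWT replicate 1. In the same library order, the 13 such genes of the second heart list had 2, 3, 31 and 3. Both subsets were chosen after the counts were seen, and choosing on low base counts favours a high ratio to those base libraries. The choice did not use SWT replicate 1, so it cannot account for the gap between control replicate 2 and SWT replicate 1. That gap rests on 1 library with high counts and on genes near the floor. The explanation stays open.

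In cells labelled as SH-SY5Y, 15 of 29 noradrenergic genes lacked counts and 5 reached 10 CPM in every library, HAND2 and GATA2 among them. Loss of genes by annotation or counting stays open: 20 of 29 noradrenergic and 1 of 30 mesenchymal genes stayed under 1 CPM in every library, but that count restates the pattern, and IER3, an immediate early gene, had 0 counts in all 4 libraries as well. A mesenchymal state of the labelled line and another cell line were not told apart here, because both may give the 25 mesenchymal genes at 10 CPM or more. No genes beyond these marker lists were examined for this question, and genotypes were not used. No biological explanation was tested, since all 4 samples carry 1 cell line label.

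Ribosomal protein and respiratory chain genes were lower in SWT by small amounts, and across 6320 genes the log2 fold change correlated with transcript length (Spearman rho 0.287) and more strongly with GC content (-0.401). With the length and GC trend removed, the ribosomal median moved from -0.073 to -0.044 (interquartile range 0.066), and the list stayed past the threshold (camera adjusted p = 1.57e-04). Length and GC content were those of each gene's longest annotated transcript, which need not be the one expressed. The trend may thus have been removed only in part, so this test cannot exclude it as the cause. Differences between any 2 libraries stay open, since the list's median differed by at most 0.013 within a group, but each group gives 1 such difference and no spread for it. For the respiratory chain the median moved from -0.045 to -0.032 (interquartile range 0.10) and the call ended at an adjusted p of 0.0679, for a cause that was not tested, so the trend cannot be told apart from a change after treatment. An effect of treatment stays a hypothesis for both lists, and the missing call of the ribosomal list with an estimated correlation does not count against it, since that test called 0 of 10 simulations with a true ribosomal shift of -0.1.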
